A study of Mus musculus with 6 samples.

How the data were processed

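RNA from mouse cardiac ventricles was measured by bulk RNA sequencing in 6 libraries. According to the labels, 3 libraries came from control mice that carried a Cre recombinase under the alphaMHC promoter with unmodified β-catenin, and 3 from mice with stabilized β-catenin. The deposited table holds 24015 gene rows and a column for each of the 6 libraries, and 0 columns of per-sample values were left unused. The columns are marked by group and by a letter, whereas the labels number the replicates, so a column could be assigned to its group but not to a numbered replicate. The libraries are therefore named by group and letter. The labels do not say whether each library came from a separate animal. The p-values of single genes therefore measure the spread between these libraries, which may in part be technical.

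The deposited values are on a log2-like scale. Per the submitters' processing notes, reads were aligned to mm9 with Bowtie2 2.0 and processed with DESeq2, whose version is not given in the sources used here. Per the name under which the table was deposited, its log2-scale values are counts after the authors' variance-stabilizing transformation. The read counter, its treatment of strand and of reads with several matches, the gene annotation and the filters are not given in the sources used here. The table has a lowest value of 4.9024, which stands for a count of 0, and a highest value of 20.9544. In all 6 libraries 6093 genes lie at the lowest value. Because the transformation has a closed form, the deposited values were inverted to normalized counts. Of the values above the lowest, 100% came out as whole multiples of a single step per library, within a tolerance of 0.01 reads. This gave each library's whole reads, its size factor and its depth, from 14945509 to 23203230 reads assigned to genes. Levels are given as normalized counts, meaning reads divided by the authors' size factor, as mean ± SD over n = 3 libraries. A gene with 0 reads in a library could still hold up to 3 reads, or 3 in 14945509 at the lowest depth, which covers counting error only.

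The table names genes by symbol. In 27 rows a spreadsheet had turned the symbol into a date, and 2 such symbols occur more than once. These rows stayed in the tests and are not named. The reference at hand was another mouse assembly, GRCm38, so no coordinates are printed. It was used for transcript GC content and length, which 23612 genes had, and for which genes neighbour Ctnnb1. Reads of near-identical genes, such as Myh6 and Myh7, and of overlapping genes on opposite strands cannot be told apart here, and the values of such genes are uncertain to that extent.

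Genes were tested with limma 3.58.1 in R 4.3.3 on the deposited values (lmFit, then eBayes with a mean-variance trend), with all 6 libraries in 1 fit, no covariate and two-sided p-values. Genes entered when their mean was at least 1 log2 unit above the lowest value, which kept 12597 and removed 11418. Benjamini-Hochberg adjusted p-values under 0.05 counted as passing. The log2 change is stabilized minus control on the variance-stabilized scale, which understates changes of genes with low counts, so ratios of mean normalized counts stand beside it. The design was set for variance-stabilized values, and the table held these.

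Before the data were examined, 32 gene lists were fixed, covering Wnt signalling, cardiac function, metabolism, stress responses and markers of other cell types. The 28 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 28. Camera compares a list with all other tested genes. At the preset, its p does not use how strongly the genes of a list vary together across these libraries. Camera with an estimated correlation, rank-based camera and fry were run as alternatives. Fry's directional p asks whether the genes of a list move on balance to 1 side, and its mixed p whether they change in either direction. Neither compares the list with other genes. A count adjusted over the list alone uses only that list's p-values. The 10 genes with the largest rise and the 10 with the largest fall among passing genes whose groups do not overlap, up to 4 members with the smallest p of each list, and Ctnnb1, Axin2, Lef1, Tcf7l2, Gata4, Klf15, Nppa, Nppb, Myh6 and Myh7 were to be named by a rule also fixed in advance. Symbols of predicted or clone-derived genes were counted but not named. Genes named outside this rule as examples of a change between the groups are marked as chosen after their values were seen. Tcf7 and Sp5, and genes that describe the libraries (Ttn, Rn45s, Xist and Tcap), carry no such mark.

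Alternatives fixed in advance were the low-value filter, scaling between libraries, the variance model, the scale (log2 of the inverted normalized count plus 1 or plus 8), the threshold, the set test and leaving out each library. Alternatives chosen after seeing the data were limma's voom on the recovered reads with the authors' size factors, the mean of 4 Y-linked genes as a covariate, a loess correction of each library for transcript GC content and length (span 0.5), a fit without the 2 stabilized libraries with abundant Y-linked reads, and counts of list members without control library A. The fit and the set test were first run on simulated data drawn from the real libraries' means and depths. Over 12628 tested genes, the fit recovered 42% of the genes changed 1.5-fold, 91.8% of those changed 2-fold and 100% of those changed 4-fold or 8-fold. Of its 171 calls 7 were false. In the set test on simulated data the changed list was called, and 0 of 20 unchanged lists. The simulated genes varied independently of each other and no simulated library stood apart. These rates therefore need not hold for the real libraries or lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.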

Results

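Gene expression was measured in the cardiac ventricles of C57BL/6 mice that were 15 weeks old. At 12 weeks of age the mice had been given a compound labelled TX at 30 mg/kg per day for 3 days, and tissue was taken 3 weeks later. By its labels, the control group (n = 3) carried the alphaMHC Cre recombinase, whose promoter is active in cardiomyocytes, with unmodified β-catenin. In the stabilized group (n = 3) exon 3 of β-catenin, which holds the sites that mark the protein for degradation, was deleted. Control libraries A, B and C held 16308326, 15214031 and 21542139 reads assigned to genes, and stabilized libraries A, B and C held 14945509, 17600832 and 23203230. The single comparison asks what stabilized β-catenin, the effector of canonical Wnt signalling, does to ventricular gene expression.

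The libraries differed in ways that the groups do not name. Control library A stood apart from control libraries B and C. Across tested genes, which are not independent replicates, it correlated with them at Pearson's r = 0.965 and 0.973, while B and C correlated at 0.992. Reads of Ttn, the giant sarcomere protein titin, made up 5.81% of control library A and 9.05% to 10.8% of the other libraries. Ddx3y and 3 other Y-linked genes were near 0 in all 3 control libraries and in stabilized library B, and were abundant in stabilized libraries A and C, with 2899 and 1512 normalized counts of Ddx3y. Stabilized library C also held 670 normalized counts of Xist, which is transcribed from the inactive X chromosome, against 13.2 in stabilized library A. The sex of the mice is not in the labels. Reads of the ribosomal precursor Rn45s made up 0.379% of stabilized library C and 1.87% to 7.78% of the others.

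**Figure D1:**
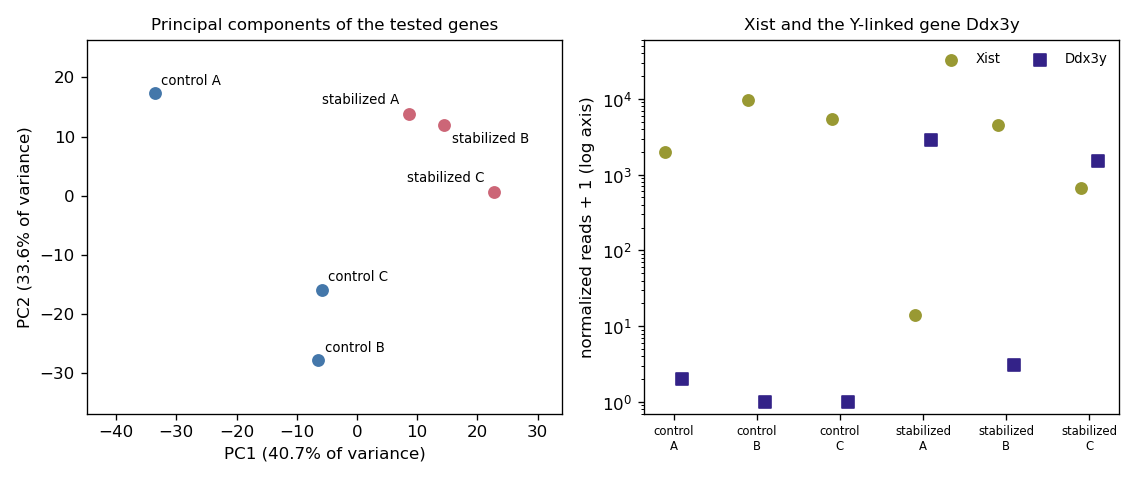
Left, scores of the 6 libraries on the first principal components of the tested genes (PC1 40.7% and PC2 33.6% of the variance; blue, control; red, stabilized). Control library A lies apart from control libraries B and C. Right, normalized reads plus 1 of Xist and the Y-linked gene Ddx3y per library on a log axis, with Ddx3y abundant in stabilized libraries A and C.

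In stabilized ventricles the Wnt feedback gene Axin2, the slow myosin gene Myh7 and most tested cell cycle genes rose, while the cardiac sodium channel gene Scn5a and the natriuretic peptide protease gene Corin fell. Axin2 went from 93.3 ± 28.3 to 770 ± 165 normalized counts (SD, n = 3 per group), an 8.25-fold rise. Myh7 went from 3909 ± 2240 to 54268 ± 30202, a 13.9-fold rise. Scn5a was 2.79-fold lower and Corin 3.52-fold lower. Of 12597 genes tested with limma, 173 were higher and 33 lower at an adjusted p under 0.05. Of these, 104 were at least 2-fold higher and 17 at least 2-fold lower on the log2 scale. In all 206 the groups did not overlap, as in 19.3% of tested genes against 10% by chance. Passing on the same values favours such genes, so this adds no support. The counts of higher and of lower genes depend on single libraries. Leaving out control library B, control library C, stabilized library B or stabilized library C gave 69, 45, 70 and 53 higher and 7, 4, 9 and 4 lower genes, and leaving out control library A gave 227 and 139. Myh7 and Corin each missed the threshold without control B, control C, stabilized B or stabilized C. Scn5a missed it without control B, control C, stabilized A or stabilized C, whereas Axin2 passed with any single library left out.

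The largest rise was that of Esr1, which encodes the estrogen receptor α. It went from 56.1 ± 10 to 64218 ± 23541 normalized counts, a log2 change of 9.15 ± 0.27 (SE; limma, adjusted p = 6.23e-06). Both groups are labelled as Cre-positive, and gene-level counts do not show which part of Esr1 the reads cover. The other large rises were those of Myh7, Edn3, Igfbp5, Adamts19, Slc22a1, Sypl2, Shank1, Axin2 and Cacna1g. Edn3, which encodes endothelin 3, rose 27.4-fold from 21.2 ± 15.8 to 583 ± 153. Igfbp5, which encodes an insulin-like growth factor binding protein, rose 7.34-fold. The organic cation transporter gene Slc22a1 rose 16.2-fold, from 23.0 ± 2.7 to 371 ± 17, with little spread between libraries. Adamts19, which encodes an extracellular metalloproteinase, rose 24.5-fold and Sypl2 24.4-fold, both from under 20 normalized counts in controls. The adjusted p of Esr1, Edn3, Adamts19, Slc22a1, Sypl2, Axin2 and Cacna1g stayed under 0.05 with any single library left out. Igfbp5 missed it without control library C, and Shank1 without control C, stabilized B or stabilized C.

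The largest falls were those of Corin, Plekhh1, Cacna1h, Scn5a, Cntn5, Kcnv2, Tbc1d10c, Pim3, Tmem100 and Ttc38. Corin, the protease that processes pro-atrial natriuretic peptide, went from 6566 ± 1832 to 1867 ± 460.5 normalized counts, a log2 change of -1.77 ± 0.26 (SE; limma, adjusted p = 0.018). Plekhh1 was 8.71-fold and Cntn5, which encodes a contactin, 8.44-fold lower, from 123 ± 35 and 100.2 ± 53.6. The kinase gene Pim3 was 2.44-fold lower. All 10 passed without control library A, but 7, 8, 2, 6 and 8 of them missed the threshold without control B, control C, stabilized A, stabilized B and stabilized C, at adjusted p-values up to 0.173.

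Ctnnb1 itself, the gene of β-catenin, had 9469 ± 585 normalized counts in controls and 9773 ± 420 in stabilized ventricles (log2 change 0.046 ± 0.13 SE; limma, adjusted p = 0.952). A gene-level count does not show whether exon 3 was deleted and so does not check the genotype labels. Tcf7l2, which encodes a transcription factor partner of β-catenin named by the study, had 192 ± 86 and 186 ± 43 (adjusted p = 0.992). Gata4, the other factor the study names, had 2109 ± 200 and 2470 ± 227 (log2 change 0.22 ± 0.13, adjusted p = 0.563). Klf15 had a log2 change of -0.35 ± 0.14 (adjusted p = 0.351).

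Of 12 tested Wnt target genes 3 rose, 0 fell and 9 did not pass, and 7 passed when adjusted over the list alone. They were Axin2, Tnfrsf19 and Wif1. Tnfrsf19, which encodes a tumour necrosis factor receptor family member, went from 121 ± 41 to 531 ± 14 normalized counts, a 4.40-fold rise (limma, adjusted p = 0.0038). Wif1, which encodes a secreted Wnt inhibitor, went from 85.8 ± 54.9 to 292 ± 25 (adjusted p = 0.0355). Wif1 missed the threshold without any single library other than control A. Sox4 was 2.70-fold higher but missed the threshold (adjusted p = 0.0506). The list lay higher as a set (camera, adjusted p = 1.64e-06), and had an adjusted p of 0.154 with an estimated correlation. Without control library A, 4 members passed. A further 8 targets lay below the filter, Lef1 among them with 2.18 ± 1.42 and 6.98 ± 3.41 normalized counts. Of those 8, Tcf7 and Sp5 passed when no filter was applied (limma, adjusted p = 0.0173 and 0.00138). Sp5 held 1 read in the controls together and 89 in the stabilized libraries.

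In the lists of Wnt pathway genes other than targets, no member passed over all genes tested. Of 22 signal transduction genes and of 20 ligands, receptors and secreted inhibitors, 0 rose and 0 fell over all genes tested, 0 and 2 passed when adjusted over the list alone, and 0 and 4 had an unadjusted p under 0.05. Wnt11 had 96.9 ± 9.3 and 180 ± 29 normalized counts (limma, adjusted p = 0.0603). Camera gave adjusted p-values of 0.645 and 0.0677. Without control library A the signal transduction list lay lower as a set (adjusted p = 0.0128). Control A was a median of 0.33 log2 units below control libraries B and C in that list. The ligand and receptor list lay higher without control B, without stabilized A and after the GC and length correction (adjusted p = 0.0196, 0.007 and 0.0196).

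**Figure D2:**
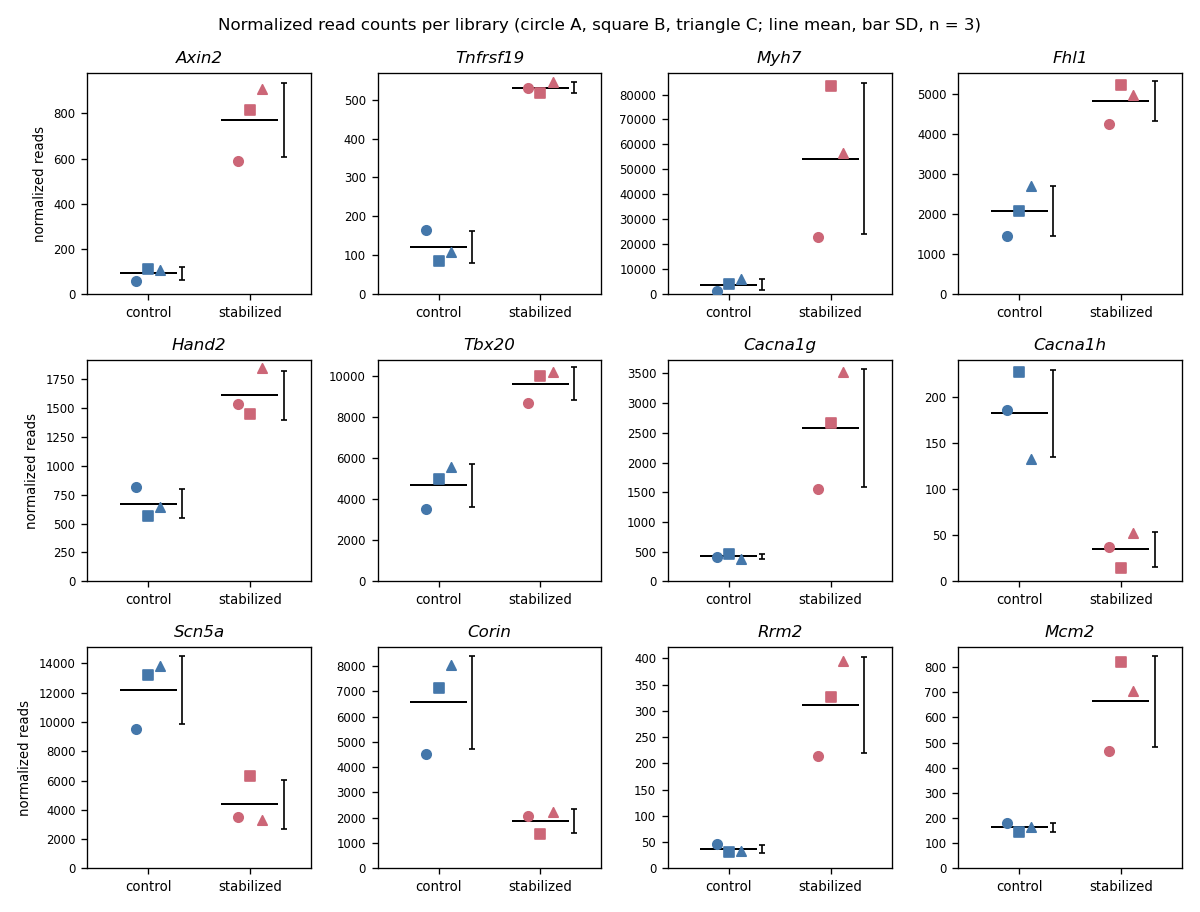
Normalized read counts per library of 12 genes in control (blue) and stabilized (red) ventricles, each axis from 0; circles, squares and triangles are libraries A, B and C, lines are means and bars SD (n = 3). Axin2, Tnfrsf19, Myh7, Fhl1, Hand2, Tbx20, Cacna1g, Rrm2 and Mcm2 lie higher and Cacna1h, Scn5a and Corin lower in all 3 stabilized libraries, while Myh7 varies from 23010 to 83289 within the stabilized group.

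Of 28 tested cell cycle genes 20 rose, 0 fell and 8 did not pass, and 27 passed when adjusted over the list alone. Rrm2, a subunit of the enzyme that makes deoxynucleotides, went from 37.0 ± 7.6 to 311 ± 92 normalized counts, an 8.42-fold rise (limma, adjusted p = 0.00369). Mcm2 and Mcm5, which encode parts of the replicative helicase, rose 4.07-fold and 3.75-fold. Ccna2, which encodes cyclin A2, rose 4.70-fold, from 51.0 ± 6.4 to 240 ± 62. The cyclin D2 gene Ccnd2, singled out after its values were seen, had the highest level of these, with 3792 ± 1413 and 19080 ± 5097. The list lay higher as a set (camera, adjusted p = 3.47e-32), and had an adjusted p of 0.354 with an estimated correlation. Fry's directional test passed for this list and the Wnt targets (adjusted p = 0.032 for each). Without control library A, 19 cell cycle genes rose. Mcm5 and Ccnd2 missed the threshold without control C or stabilized C.

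Of 16 tested fetal and hypertrophic genes, Myh7 and Fhl1 rose, 0 fell and 14 did not pass, and 3 passed when adjusted over the list alone. Fhl1, which encodes a LIM domain protein of striated muscle, rose 2.32-fold, from 2073 ± 620 to 4815 ± 505 normalized counts (limma, adjusted p = 0.0345). The α-skeletal actin gene Acta1 had 3189 ± 1990 and 12885 ± 6371 (adjusted p = 0.0824). The natriuretic peptide genes varied widely within groups. Nppa had 4692 ± 3756 and 6069 ± 7812 normalized counts and a log2 change of -0.53 ± 1.13 (adjusted p = 0.924), whose sign differs from that of the means, and Nppb had 1967 ± 715 and 3884 ± 3352 (adjusted p = 0.672). The list lay higher as a set (camera, adjusted p = 0.00135), had an adjusted p of 0.596 with an estimated correlation, and missed the threshold without stabilized library B (adjusted p = 0.0832). Control library A lay a median of 0.40 log2 units below control libraries B and C in this list. Myh7 missed the threshold without any single library other than control A and stabilized A, and Fhl1 without any other than control A and control C.

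Of 21 adult sarcomere genes 0 rose and 0 fell, 1 passed over the list alone, 3 had an unadjusted p under 0.05, and the set test missed the threshold (camera, adjusted p = 0.378). Nebl had 4276 ± 484 and 6882 ± 568 normalized counts (limma, adjusted p = 0.0595). Myh6, the fast myosin of the adult mouse heart, had 584758 ± 111035 and 505816 ± 31291, a log2 change of -0.19 ± 0.27 (adjusted p = 0.864) that was 0.24 after quantile normalization. Of 18 calcium handling genes 0 passed, also over the list alone, and 2 had an unadjusted p under 0.05 (camera, adjusted p = 0.645). Ryr2, the calcium release channel, had a log2 change of -0.58 ± 0.25 (limma, adjusted p = 0.383).

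Ion channel genes moved both ways. Of 26 tested, 2 rose, 4 fell and 20 did not pass, and 3 rose and 8 fell when adjusted over the list alone. The T-type calcium channel genes changed in opposite directions. Cacna1g went from 419 ± 41 to 2580 ± 987 normalized counts (6.16-fold higher; limma, adjusted p = 0.00606), and Cacna1h from 182 ± 47 to 34.8 ± 19.0 (5.25-fold lower, adjusted p = 0.0194). The sodium channel subunit gene Scn1b rose 2.10-fold, whereas Scn5a went from 12196 ± 2332 to 4366 ± 1656 (adjusted p = 0.0331). Among potassium channel genes, Kcnv2 was 3.05-fold lower and Kcna5 1.75-fold lower. The directional set test missed the threshold (camera, adjusted p = 0.266), and fry's mixed test passed (adjusted p = 1.16e-04). The mixed test also passed for lists without a passing member, such as fibroblast markers and p53 response genes (fry, adjusted p = 0.00779 and 0.00923). Without control library A, 3 rose and 7 fell. Scn1b missed the threshold without stabilized C and Cacna1h without control B or C. Scn5a, Kcnv2 and Kcna5 kept it without control A, and of the other single libraries only without stabilized B, only without stabilized A, and without none.

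Of 24 tested cardiac transcription factor genes, Hand2 and Tbx20 rose, 0 fell and 22 did not pass, and 2 passed over the list alone. Hand2, a factor of heart development, went from 674 ± 128 to 1612 ± 214 normalized counts, a 2.39-fold rise (limma, adjusted p = 0.014). Tbx20, a T-box factor of the heart, rose 2.06-fold (adjusted p = 0.036). Tbx20 missed the threshold without any single library other than control A, and Hand2 without control C or stabilized C. Nkx2-5 had 889 ± 79 and 1145 ± 132 (adjusted p = 0.32). The list lay higher as a set (camera, adjusted p = 0.0405). That p was 0.596 with an estimated correlation, 0.219 with array weights, 0.36 without control library A and 0.187 without stabilized library C.

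**Figure D3:**
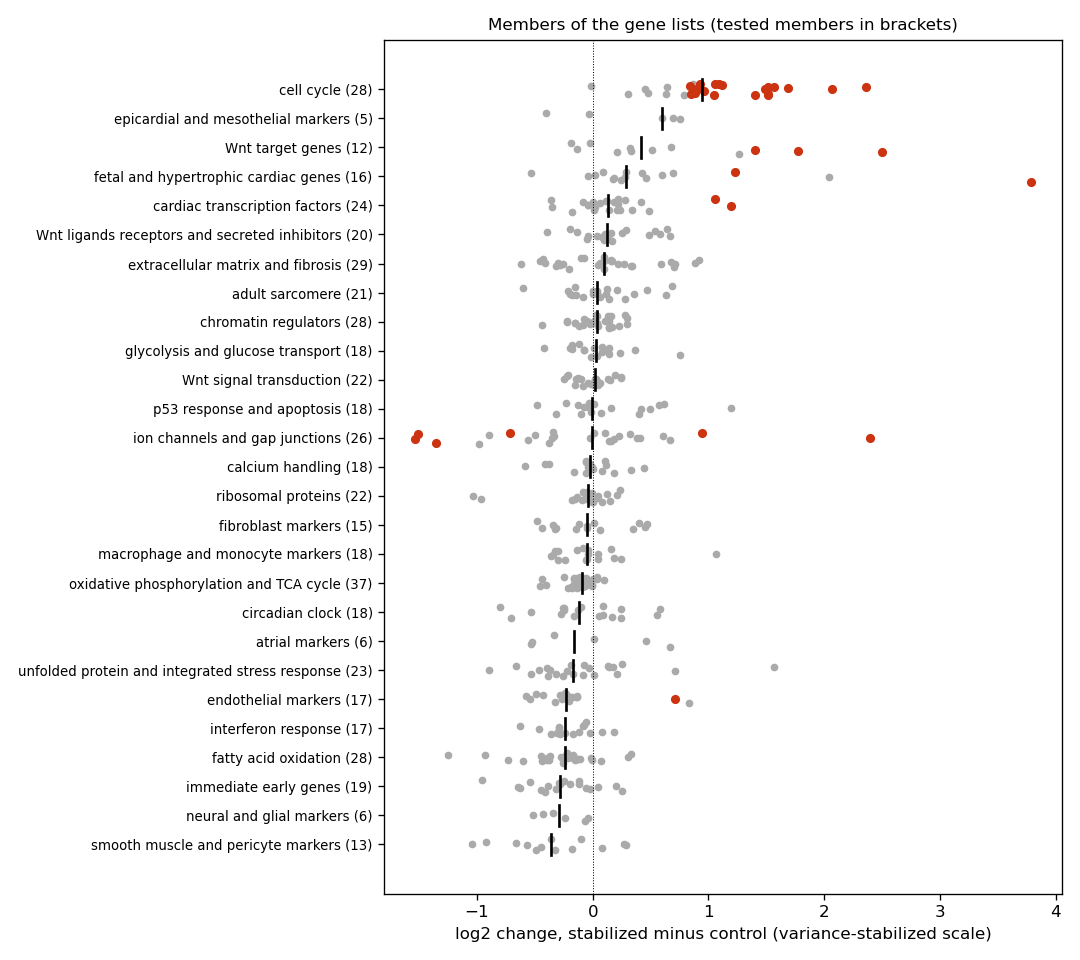
log2 change (stabilized minus control, variance-stabilized scale) of each tested member of 27 gene lists, ordered by median; points are genes, red points passed over all genes tested, black lines are list medians. Of these 27 lists cell cycle genes lie furthest to the right, with a median of 0.95, and ion channel genes spread to both sides. The sex-linked list, with a median of 3.26, is not shown.

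Fatty acid oxidation genes lay lower as a set (camera, adjusted p = 6.50e-05), and had an adjusted p of 0.596 with an estimated correlation. Over all genes 0 of the 28 tested passed, and 1 when adjusted over the list alone. Unadjusted, 7 had a p under 0.05. Of the 28, 25 had a negative log2 change, with a list median of -0.24. Pdk4, a kinase that restrains pyruvate oxidation, had 5213 ± 1956 and 2626 ± 475 normalized counts (limma, adjusted p = 0.152). The fatty acid transporter gene Slc27a1 had 2260 ± 148 and 1475 ± 155 (adjusted p = 0.0638). Control library A lay a median of 0.35 log2 units above control libraries B and C, and without it the camera adjusted p was 0.00284.

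Of 37 oxidative phosphorylation and TCA cycle genes 0 passed, also over the list alone, 1 had an unadjusted p under 0.05, and 33 had a negative log2 change. The list lay lower as a set (camera, adjusted p = 0.0405), and had adjusted p-values of 0.882 with an estimated correlation and 0.184 with array weights. It was 0.0579 after quantile normalization. Control library A lay a median of 0.40 log2 units above control libraries B and C in these genes. Without it the list median was 0.018 instead of -0.097 and the camera adjusted p was 0.803. The list also missed the threshold without stabilized B or C (adjusted p = 0.15 and 0.312). Of 18 glycolysis and glucose transport genes 0 passed and 2 had an unadjusted p under 0.05 (camera, adjusted p = 0.784), and the glucose transporter gene Slc2a4 had 10679 ± 948 and 8040 ± 1752 normalized counts.

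Immediate early genes lay lower as a set (camera, adjusted p = 2.26e-04), and had adjusted p-values of 0.596 with an estimated correlation and 0.0804 with array weights. Of the 19 tested 0 passed over all genes and 7 were lower when adjusted over the list alone, the same number as at an unadjusted p under 0.05. Klf4 had 588 ± 18 and 363 ± 52 normalized counts (limma, adjusted p = 0.0562), and Fos had 68.6 ± 19.3 and 28.5 ± 4.1 (adjusted p = 0.0912). Interferon response genes also lay lower as a set (camera, adjusted p = 0.002), with 0 of 17 past the threshold over all genes, 1 over the list alone and 5 at an unadjusted p under 0.05. This set had adjusted p-values of 0.596 with an estimated correlation and 0.115 with array weights. Irf7 had 214 ± 44 and 119 ± 15 (limma, adjusted p = 0.0939). The interferon list missed the threshold without control A or stabilized A (adjusted p = 0.0541 and 0.0593).

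In the lists of unfolded protein and integrated stress response, p53 response and apoptosis, circadian clock, chromatin regulator and ribosomal protein genes, 0 of 23, 18, 18, 28 and 22 tested members passed over all genes, and 6, 5, 2, 2 and 2 had an unadjusted p under 0.05. Over the list alone 1 member was higher and 1 lower in each of the stress and p53 lists, and 0 passed in the other lists. Camera gave adjusted p-values of 0.137, 0.546, 0.645, 0.784 and 0.462. The stress list lay lower without control B and with the stricter filter (adjusted p = 0.0196 and 0.0412), and without control B so did the ribosomal list (adjusted p = 0.0196). The median and the mean of the p53 list differed in sign, at -0.0020 and 0.14. Its member Bcl2, which encodes an inhibitor of apoptosis, had 387 ± 95 and 971 ± 303 normalized counts (limma, adjusted p = 0.063).

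Among markers of other cell types, 2 lists passed as sets. Endothelial markers lay lower as a set (camera, adjusted p = 0.0307; median log2 change -0.23), yet the single member of 17 that passed, Vwf, rose. The set had adjusted p-values of 0.651 with an estimated correlation and 0.128 with array weights. Vwf, which encodes von Willebrand factor, went from 1938 ± 12 to 3231 ± 421 normalized counts (limma, adjusted p = 0.038), and missed the threshold without control B, control C, stabilized B or stabilized C. Over the list alone 2 endothelial markers were higher and 1 lower. Smooth muscle and pericyte markers lay lower as a set (camera, adjusted p = 0.00726), with 0 of 13 past the threshold and 5 at an unadjusted p under 0.05. The set had adjusted p-values of 0.651 with an estimated correlation and 0.0816 with array weights. Tagln had 403 ± 160 and 179 ± 25 (limma, adjusted p = 0.143). Without control B the camera adjusted p-values of the endothelial and smooth muscle sets were 0.269 and 0.101, the endothelial p was 0.192 without stabilized A, and the smooth muscle p was 0.0526 without stabilized B.

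Of the 15 fibroblast, 18 macrophage and monocyte, 5 epicardial, 6 neural and 6 atrial markers tested 0 passed, and 5, 3, 4, 1 and 2 had an unadjusted p under 0.05. Over the list alone 3 epicardial markers were higher and 1 lower, and 0 passed in the other marker lists named here. Camera gave adjusted p-values of 0.462, 0.378, 0.252, 0.0907 and 0.892. Without control B the macrophage list lay lower (adjusted p = 0.0075), without stabilized B or without a filter the epicardial list higher (adjusted p = 0.0472 and 0.0163), and without stabilized A the neural list lower (adjusted p = 0.0102). Control library A lay a median of 0.41 log2 units above control libraries B and C in macrophage markers. Of 29 extracellular matrix and fibrosis genes 0 passed, also over the list alone, and 4 had an unadjusted p under 0.05 (camera, adjusted p = 0.645). Without stabilized library A the matrix list lay higher (adjusted p = 0.012). Lox, which crosslinks collagen, had 77.9 ± 12.9 and 161 ± 38 normalized counts (limma, adjusted p = 0.082). Too few members were tested of the lymphocyte and neutrophil (0), adipocyte (3), skeletal muscle (3) and erythroid (3) lists. The 5 sex-linked genes lay higher as a set (camera, adjusted p = 0.0408), with 0 past the threshold, 4 over the list alone and 4 at an unadjusted p under 0.05. Its adjusted p was 0.596 with an estimated correlation, 0.128 with array weights, and 0.113, 0.0868, 0.117 and 0.122 without control A, control C, stabilized A or stabilized C.

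In each tested list with 0 members past the threshold, limma's voom on the recovered reads also called 0. In the cell cycle list voom called 16 genes higher, against 20 with limma on the deposited values. Camera called 11 of the 28 lists. None was called with an estimated correlation, which gave adjusted p-values from 0.154 upward, and fry called 2. With the mean of the Y-linked genes as a covariate, 42 genes were higher and 9 lower, of which 33 and 3 were also called without it. The group difference in that fit rests mainly on stabilized library B. Its Y-linked mean of 5.06 lies near the 4.90 to 5.13 of the controls, against 10.2 and 9.64 in stabilized libraries A and C. Of the 42 named genes that passed, 30 missed the threshold with that covariate, while Esr1, Edn3, Slc22a1, Sypl2, Axin2, Cacna1h, Rrm2, Mcm2 and Mcm5 were among those that passed. Over the 42 named genes that passed, the largest adjusted p with a single library left out was 0.182.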

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

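The voom, Y-linked covariate and GC and length alternatives and the fit without stabilized libraries A and C were chosen after seeing the data. No paired analysis was possible because the table's columns carry letters and not the replicate numbers of the labels, so the planned fit with the replicate number as a block was not run. Scaling, trend, robust fitting, the inverted scale with 1 or 8 added, no filter, voom and a 1.5-fold minimum each gave 166 to 207 higher and 33 to 43 lower genes, against 173 and 33. The stricter filter gave 84 and 21. Array weights, which gave control libraries A, B and C weights of 0.212, 0.720 and 4.48, gave 535 and 470. The control group in that fit rested mainly on control library C. The Y-linked covariate gave 42 and 9. In that fit stabilized library B carries most of the group difference, so it is not independent of the fit without stabilized libraries A and C. Without stabilized libraries A and C, where the lone stabilized library is assumed to vary like the controls, 78 and 10 genes passed, 62 and 2 of them also in the full fit. The GC and length correction gave 203 and 76, and an adjusted p under 0.10 gave 259 and 109. Leaving out 1 library gave 45 (control C) to 227 (control A) higher and 4 (control C or stabilized C) to 139 (control A) lower genes. The share of calls that were higher was 84.0%, but 62.0% without control A, 53.2% with array weights and 72.8% after the GC and length correction. Lists past the threshold numbered 11, with 8 to 13 when 1 library was left out, 4 with array weights, 2 with fry and 0 with an estimated correlation (smallest adjusted p 0.154, with 2 lists at an unadjusted p under 0.05). The matrix list lay higher with the Y-linked covariate (adjusted p = 1.54e-07) and without stabilized A and C (1.60e-07), as did the ligand list (0.00493 and 0.00601). The ion channel and neural lists lay lower (0.0159 and 0.0204 with the covariate). The transcription factor, endothelial and interferon lists missed the threshold with the covariate (0.251, 0.715 and 0.575). Of 42 named genes that passed, 15 also passed with each library left out in turn, and 0, 17, 23, 6, 16 and 24 were lost without control A, B, C, stabilized A, B and C. The Y-linked covariate lost 30 of the 42, and the fit without stabilized A and C lost 25. Genes that turned direction had missed the threshold throughout. These were Ctnnb1 (-0.027 with array weights), Tcf7l2 (-0.30 with array weights, -0.12 without stabilized C and from -0.31 without control A to 0.22 without control C over the libraries left out, -0.14 with the covariate, -0.020 after the GC and length correction, -0.18 without stabilized A and C), Nppa (0.08 without control C and from -1.77 without stabilized B to 0.77 without stabilized A, 2.19 with the covariate, 1.95 without stabilized A and C), Myh6 (0.24 after quantile normalization) and Xist (0.24 with the covariate, against -3.06). The cause was not tested, except that leaving out libraries leaves fewer samples and a stricter filter fewer genes. Depth limits genes with few reads, such as Lef1 with 6 reads in the controls together and 24 in the stabilized libraries.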

Other observations

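The tests of transgene expression in all 6 libraries, of Esr1 in the stabilized library with few Y-linked reads, of sex as the cause of the calls and of diluted cardiomyocyte RNA were chosen after the results were seen, as were the genes named in the next paragraph. The other tests were fixed before their results were seen.

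Of the 206 genes that passed, 172 belonged to none of the fixed lists. They include further genes of cell division and DNA replication that the cell cycle list did not hold, such as Hmmr, Prc1, Aspm, Kif20a, Cdt1, Chek1, Rad51 and Gins2, all higher. The 172 are thus not all apart from the cell cycle genes. Some others are described here one by one, without a test of any shared function. Wisp1, a matricellular protein gene named for its induction by Wnt, rose 6.96-fold, from 62.8 ± 16.7 to 437 ± 51 normalized counts (SD, n = 3; limma, adjusted p = 0.00133). Bambi, a decoy receptor for the transforming growth factor β family, rose 4.44-fold, from 315 ± 85 to 1402 ± 36. Fst, which encodes the activin antagonist follistatin, went from 3.51 ± 1.24 to 114 ± 29 and Spry2, which restrains receptor tyrosine kinase signals, rose 2.18-fold. Genes that fell included Lipe, the hormone-sensitive lipase gene, from 727 ± 58 to 386 ± 23 (adjusted p = 0.0151), the adenosine A1 receptor gene Adora1, from 314 ± 21 to 155 ± 16, and the neighbouring kinase genes Sbk2 and Sbk3, 3.08-fold and 2.98-fold lower. Wisp1, Bambi and Fst passed with any single library left out. Spry2 missed the threshold without control C or stabilized C, Adora1 also without control B, and Lipe, Sbk2 and Sbk3 without control B, control C, stabilized B or stabilized C.

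Esr1 went from rank 10850 by control mean to rank 21 by stabilized mean, at a mean of 0.364% of all reads. Reads of an inducible Cre transgene that carries Esr1 sequence are a candidate explanation, because such fusions are switched by estrogen receptor ligands. If so, estrogen response genes need not move, and 13 tested genes of a list fixed beforehand did not pass (limma's camera, adjusted p = 0.17984 as the only list in its family), which leaves this and a rise of the endogenous gene open, since reads per exon were not analysed here. Such a transgene expressed alike in all 6 libraries, as their Cre-positive labels would give, is argued against by the lowest stabilized count being 583.661 times the highest control count. That lowest count was in stabilized library B, which holds few Y-linked reads, so the sex of the mice is argued against as well (the same ratio, 583.661), while Greb1, an estrogen response gene left out of the list because its value had been seen, rose 6.96-fold (limma, adjusted p = 0.00606).

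Control library A deviated from the mean of the other libraries of its group with an SD of 0.431 log2 units across genes, against 0.233 to 0.310 in the other 5 libraries. A dependence on transcript length is a candidate explanation, since Spearman's rho across genes of the deviation with length was -0.587123, against -0.246, -0.167 and 0.431 in stabilized libraries A, B and C (control B and C had 0.524 and 0.359, not independent of A, which is part of their reference), and correcting for GC content and length lowered the SD to 0.813 of its value. Dilution of cardiomyocyte RNA by other cells is argued against as the sole cause. Of 21 sarcomere genes 7 were over 0.3 log2 units higher and 5 over 0.3 lower, among them Tcap at 1.11 and Ttn at -1.10. Dilution in part stays open, since a dependence on length could itself spread these genes both ways. A larger share of immune cell RNA stays open, because macrophage markers had a median deviation of 0.412303, between the bounds set for the test, while endothelial markers had -0.107 and lymphocyte markers were too low to test. A shift of that size was not particular to immune markers. Ribosomal protein genes had 0.454 and oxidative phosphorylation and TCA cycle genes 0.405, while chromatin regulators had -0.336. The labels name no biological difference within the group, and none was tested beyond these shares of cells.

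The 206 calls came from the real grouping, and the highest count in any other of the 10 splits of the 6 libraries was 0, but with 1 of 10 splits as large the design cannot give a share under 0.05. At an unadjusted p under 0.05 the real grouping gave 1592 genes and the split of control A, stabilized A and stabilized B from the rest 1963, which points to a structure of the samples other than the groups. Sex as the whole cause of the calls is argued against by a ratio of 0.961776. In the 79 genes called without stabilized library B, it is that library's median distance from the control mean over the other stabilized libraries'. The ratio was over 0.5 in 73 genes, and noise of the shared control mean alone would give 0.4. A part of sex in other calls stays open. The Y-linked covariate left 33 and 3 of the calls, but its group difference rests mainly on stabilized library B, so the losses do not decide this. A strain segment carried along with the modified Ctnnb1 allele may add calls nearby. Of the 100 tested genes nearest Ctnnb1 only 2 were called, Scn5a and Itga9 (2% against 1.62% of the other genes, two-sided Fisher's exact test, p = 0.679). This argues against a large excess of calls among those 100 genes. It leaves open those 2 calls and a longer segment. What stays open is β-catenin stabilization itself, as a hypothesis, beside any difference between the groups that the labels do not record. If the Esr1 reads come from a Cre transgene, its expression differed between the groups, although both are labelled Cre-positive. The calls could then not be told apart from an effect of that transgene.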
